A study of Oryza sativa with 4 samples.

How the data were processed

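Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on young rice seedlings of the indica cultivar Pusa Basmati 1 that overexpress OsMADS27 with an N-terminal triple Myc tag. Per the labels, sonicated chromatin was pulled down on Myc-Trap magnetic agarose, and the DNA was sequenced from one end. The 4 samples are 2 pulled-down libraries and 2 libraries of input chromatin, grouped and numbered by their titles. A peak list was used for each pulled-down library. The input libraries enter through those lists, as the control of the same number.

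Per the submitters' processing notes, the authors trimmed reads with cutadapt and called peaks with MACS2. Per the file headers, MACS version 2.2.5 was run separately on each replicate against its own input, with narrow peaks, a q cutoff of 0.05, an effective genome size of 400 Mb and regional background windows of 1000 and 10000 bp. Per the file headers, tags were 50 bp long, the fragment length was set to 50 bp although the labels give sonicated fragments of 200 to 500 bp, and at most 5 tags were kept at one position. Tags were therefore not extended, and no position can hold more than 500 tags (50 bp, both strands, 5 tags each). The minimum peak length equals the fragment length of 50 bp, per the file headers. The aligner, the treatment of reads with several matches and the genome build are not given in the sources used here. A directory name in the headers holds the word Bowtie.

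The deposited pileup is a signal: the number of tags over the summit, which the authors' software scaled to the smaller library. The scale was 0.960 in replicate 1 and 0.981 in replicate 2, and after division by it 100% of the pileups in both lists were whole numbers within 0.02 of a tag. The deposited fold enrichment is a ratio of the pileup plus 1 to the local input background plus 1. The deposited p and q are −log10 values from a Poisson test of that pileup against that background. Peak start, end and length are in base pairs, and positions are 1-based as in the lists. The local input background in tags was recomputed from pileup and fold enrichment. With it, the deposited −log10 p was recovered within 2% for 100% and 99.9% of the peaks of replicates 1 and 2. In 93.5% and 93.4% of peaks the recomputed background was a whole number within 0.02 of a tag, as for the input tags over the summit itself. In the others it was a regional or genome-wide average.

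Depth came from the file headers. Replicate 1 had 171891240 pulled-down tags, of which 136923044 were kept, and 162741825 input tags, of which 131452322 were kept. Replicate 2 had 161362336 pulled-down tags (130482505 kept) and 157206538 input tags (127964706 kept). The kept input tags give a genome-wide average of 16.4 and 16.0 tags over a position. Exact Poisson intervals of tag numbers and Wilson intervals of shares are at 95% and cover counting error only.

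A peak was called shared when it overlapped a peak of the other list by at least 50% of the shorter of the pair. The number of shared peaks was compared with 200 random placements of the replicate 2 intervals on the same sequences (a one-sided permutation test of positions, smallest possible p 0.00498). Each sequence was taken to end at the largest peak end of either list, since chromosome lengths and assembly gaps were not used here. Agreement of fold enrichment was described by correlations across shared peaks, which are not independent replicates, so no p-value is given. On simulated lists of 72738 peaks, made from the replicate 1 list with 60.0% of the intervals kept in place, the overlap code recovered 100% of those kept and called 1.16% of the moved ones shared. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

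Test designs, gene lists and most alternatives were fixed before the data were examined. Comparisons with promoters, gene lists, gene classes, sequence motifs and the OsMADS27 locus itself were among them and were not made, because they need the genome and annotation of the build of the lists, and the gene table used for names is of another assembly (ASM3414082v1). No peak was therefore assigned to a gene. In that case the rule fixed in advance names the 12 shared peaks with the highest smaller-of-both fold enrichment, by position. The limit of 2 times the genome-wide input background, the sets of identical peaks and the comparison of tag numbers between replicates were chosen after the data were examined.

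The replicates were compared before use. Over 44503 distinct shared peaks with summits at most 50 bp apart and a whole-number background, the difference in pulled-down tags between the replicates had a variance 0.581 times that of Poisson sampling, and the input background 0.793 times. For the pulled-down tags of one common source, the limit of 5 tags per position gives a value of 0.665. That value takes tags as spread evenly over the positions, and an uneven spread was not modelled. The 44503 pairs were selected by a call in both lists with close summits, which can lower the ratios by an amount not measured here. No other pulled-down pair was analysed, so the ratios do not show whether the replicates are one library. The libraries were kept as the 2 replicates of their labels, and both values are given side by side, with no SD. The labels do not say whether they came from separate plants or pull-downs, so agreement between the lists, and the p-values of their overlap, may measure technical repeatability only.

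Chance identity of peaks was tested by permuting replicate 2 partners 100 times among pairs grouped by replicate 1 values, in 5 groupings. Groups spanned 50, 20 or 10 tags and 25, 10 or 5 tags of background, and in 2 of the groupings also 20 or 10 bp of width. After permutation Spearman's rho of fold enrichment between the lists was 0.74 to 0.82. True copies stay in one group and can meet again, so these numbers overstate chance, most of all in the narrowest grouping, with a median of 2 pairs per group.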

Results

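OsMADS27 is a MADS-domain transcription factor of rice, and members of this family bind CArG boxes in DNA. The series asked where in the genome the protein binds, as part of work on modules of nitrate response. Myc-tagged OsMADS27 was pulled down from chromatin of young transgenic seedlings grown without further treatment, and the sequenced DNA was compared with input chromatin of the same number. The pulled-down libraries held 136923044 and 130482505 tags after removal of excess duplicates, and the inputs 131452322 and 127964706. Values of both replicates are given side by side, with no SD; the labels do not say whether they came from separate plants or pull-downs.

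The lists held 72738 peaks in replicate 1 and 73366 in replicate 2, spread over all 12 chromosomes and 39 unplaced sequences. Enrichment over input was low at most of them. The median fold enrichment, as called by the authors, was 1.79 in replicate 1 (quartiles 1.52 and 2.12) and 1.83 in replicate 2 (quartiles 1.545 and 2.18). A fold of 2 or more was reached by 23786 peaks (32.7%) in replicate 1 and 26792 (36.5%) in replicate 2, a fold of 3 or more by 1565 (2.15%) and 2226 (3.03%), and a fold of 4 or more by 77 and 104. As called with a fragment length of 50 bp, peaks were narrow, with a median of 90 bp in both lists, and covered 7.64 and 7.79 Mb. The median summit held 274 and 265 tags.

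Most regions were found in both lists. Of the replicate 1 peaks, 56179 (77.2%) had a partner in replicate 2, and of the replicate 2 peaks 55934 (76.2%) had one in replicate 1. Random placement of the replicate 2 peaks gave 2007 shared peaks on average and 2105 at most, so the observed number was 28 times higher (permutation test by random placement, one-sided p = 0.00498, the smallest it can give). Placement within 10 to 50 kb of each peak's own position, which keeps the regional density, gave a ratio of 21.2. Neither placement kept the input background at a peak, so sites of high background listed in both replicates would also raise these ratios. The summits of a pair lay a median of 1 bp apart, and 80.6% lay within 10 bp.

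Fold enrichment of the shared regions was similar in both lists. Across shared peaks Spearman's rho was 0.82 for fold enrichment and Pearson's r was 0.82 for its log2 value; peaks are not independent replicates. Part of this agreement ran with the input background, whose rho between the lists was 0.97. Within bands of background, taken as the mean of both lists, rho for fold enrichment was 0.43 below 2 times the genome-wide average (1070 pairs), 0.62 from 2 to 5 times (8567 pairs), and 0.73 at 15 times and above (9155 pairs). Of the peaks with a fold of at least 3, 1051 of 1565 in replicate 1 (67.2%) and 1428 of 2226 in replicate 2 (64.2%) had a partner of any fold in the other list. With both lists limited to folds of at least 3, 440 of the 1565 in replicate 1 (28.1%) had a partner. Their partners were 19.8% of the 2226 in replicate 2, and rho over this limited range was 0.25. Within bands of background up to 10 times the average, peaks of such folds were shared more often than those of the lowest folds. From 2 to 5 times, 77.3% and 71.2% of them had a partner, against 39.7% and 49.9% at folds of 1 to 1.5. From 5 to 10 times the shares were 88.3% and 90.7%, against 59.6% and 62.8%.

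**Figure D1:**
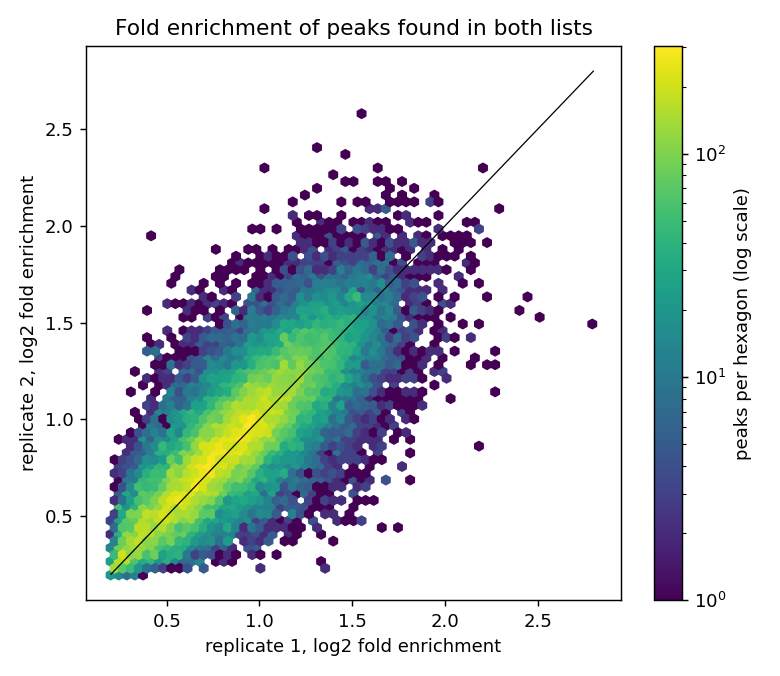
Log2 fold enrichment over input of the 56179 shared peaks, replicate 1 on the x axis and replicate 2 on the y axis, with the colour of each hexagon giving the number of peaks on a log scale and the line marking equal values. The cloud follows the line (Spearman's rho 0.82) and widens toward high folds, where single peaks lie far from it.

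Sharing rose with background and with width. Peaks at under 2 times the genome-wide background were shared in 39.4% of cases in replicate 1 (95% Wilson interval 37.6 to 41.3%, 2703 peaks) and 36.9% in replicate 2 (35.2 to 38.7%, 2925 peaks). At 10 to 15 times the background the shares were 84.1% and 83.6%, and at 15 times and above 84.6% and 81.1%, the latter below the preceding band. Peaks of 50 to 60 bp were shared in 60.6% and 56.2% of cases, and peaks of 200 bp or more in 98.0% and 98.1%. A wide peak meets the rule of 50% of the shorter peak more easily, and the width bands were not repeated under another rule. A peak without a partner was not listed in the other replicate, which does not show absence of enrichment there: peaks under 2 times the background held a median of 61 and 59 tags, and the lowest fold called among them was 1.55 in both lists.

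**Figure D2:**
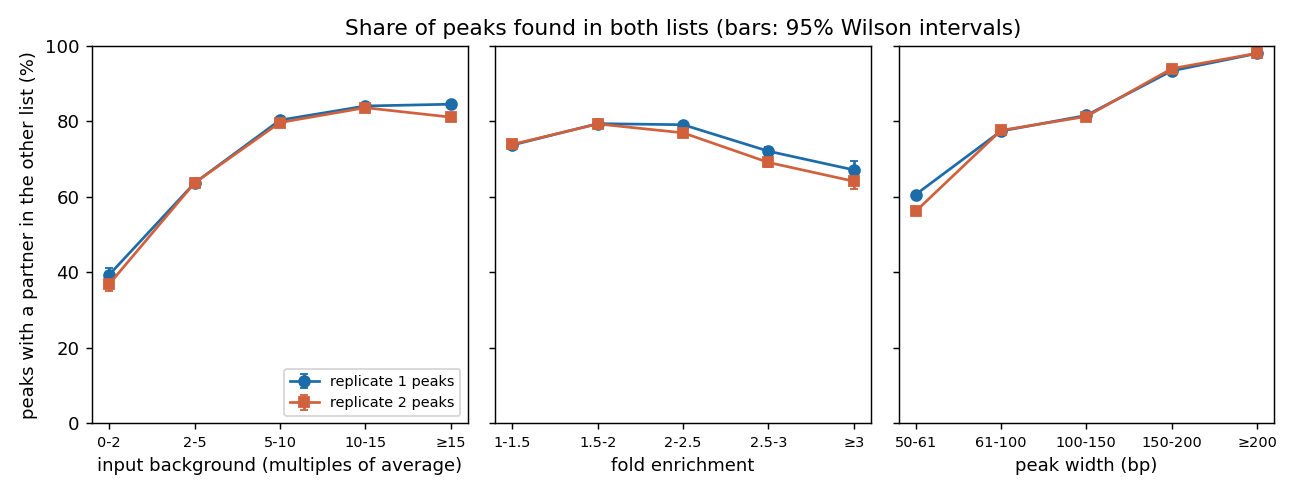
Percent of peaks of each list with a partner in the other list, in bands of input background (multiples of the genome-wide average), fold enrichment and peak width; bars are 95% Wilson intervals, mostly smaller than the symbols. The share rises from 39.4% to 84.6% with background and from 60.6% to 98.0% with width in replicate 1.

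The 12 named regions, those with the highest smaller-of-both fold enrichment, lay on 8 chromosomes, were 51 to 286 bp wide and had folds from 3.89 upward in both lists. Coordinates are those of the lists, whose build is not given in the sources used here. Names of unplaced sequences in the lists start with Syng_TIGR, AC or AP, and Syng_TIGR names occur in assemblies of the japonica cultivar Nipponbare, whereas the plants were indica. The first was on chromosome 11 at 22338244 to 22338305, with 132 tags in replicate 1 (95% exact Poisson interval 110 to 157) over a background of 27, and 119 tags in replicate 2 (98.6 to 142) over 23.0. Its folds were 4.56 and 4.90. On chromosome 4, the region 28794622 to 28794672 held 88 tags (70.6 to 108) and 93 tags (75.1 to 114) over backgrounds of 16.4 and 21.0, close to the genome-wide average, with folds of 4.90 and 4.19. On chromosome 3, the region 9059410 to 9059466 held 191 and 178 tags, with folds of 4.53 and 4.08. On chromosome 6, the region 7978399 to 7978634 held 288 and 244 tags over backgrounds of 62.0 and 58.5, with folds of 4.40 and 4.04 and the highest −log10 q of the group, 80.1 and 64.2.

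The other 8 named regions had folds of 3.89 to 4.56 in replicate 1. They were chromosome 3 at 2050578 to 2050638 (folds 4.49 and 3.99), chromosome 1 at 31901886 to 31901939 (4.55 and 3.98), chromosome 1 at 31544892 to 31545048 (4.56 and 3.95) and chromosome 5 at 23024959 to 23025028 (3.93 and 4.14). The remaining ones were chromosome 2 at 19772644 to 19772739 (3.90 and 3.96), chromosome 1 at 2305882 to 2306167 (4.2 and 3.90), chromosome 3 at 6314080 to 6314140 (4.00 and 3.89) and chromosome 10 at 21001328 to 21001381 (3.89 and 4.01). The named regions on chromosome 6 and at 2305882 on chromosome 1 had the same tag numbers, 288 and 244, as each other and as regions on chromosome 3 (35639867 to 35639937) and chromosome 7 (22520537 to 22520733). The lowest −log10 q among the 12 in either list was 18.2. In 6 of the 12, the background was under 2 times the genome-wide average in both lists.

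The highest folds of a single list were not matched in the other. On chromosome 1, the region 31983883 to 31983960 had a fold of 7.04 in replicate 1 (153 tags over a background of 20) and 2.81 in replicate 2 (125 tags over 43.0). On the same chromosome, 5997609 to 5997735 had a fold of 5.98 in replicate 2 (138 tags over 21.8) and 2.96 in replicate 1 (141 tags over 45.0). At both regions the input background differed more between the replicates than the pulled-down tags did. Both were picked for the highest fold of 1 list, which favours a low input background in that list. Other high folds had no partner to compare: 5.76 on chromosome 5 at 27854636 to 27854695 in replicate 1, and 5.21 on chromosome 4 at 8817326 to 8817432 in replicate 2.

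Peak density differed between chromosomes by more than between the replicates. Chromosome 4 held 246 and 251 peaks per Mb and chromosome 5 held 231 and 237, against 140 and 143 on chromosome 3 and 146 and 146 on chromosome 2. The ratio of chromosome 4 to chromosome 3 was 1.75 in replicate 1 and 1.76 in replicate 2, and no chromosome differed between the replicates by more than 2.89% of the mean of both. Peaks at under 2 times the genome-wide background were spread more evenly, at 6.03 to 8.85 per Mb in replicate 1 and 6.29 to 9.32 in replicate 2. For these the ratio of chromosome 4 to chromosome 3 was 1.16 and 0.941, on either side of 1. Along the chromosomes, the 740 full windows of 500 kb held a median of 88 peaks in both lists. The densest was on chromosome 5 from 9.5 to 10 Mb, with 353 and 386 peaks, and the window with the lowest mean of both lists was on chromosome 1 from 7.0 to 7.5 Mb, with 9 and 7.

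**Figure D3:**
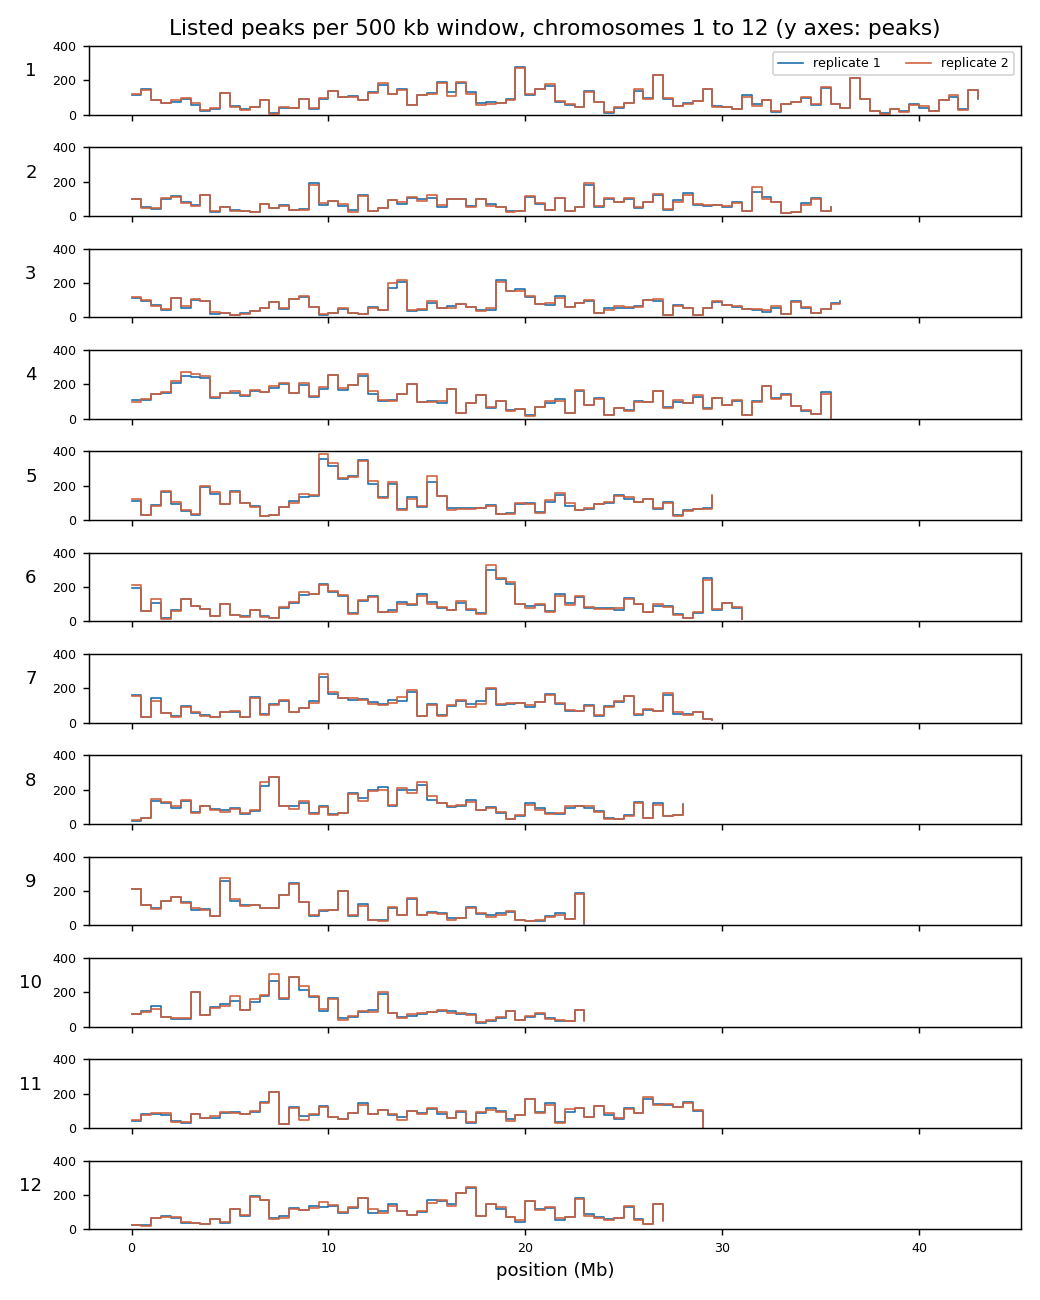
Number of listed peaks per 500 kb window (y axis) along chromosomes 1 to 12 (x axis, Mb) in replicate 1 and replicate 2. Both lists trace the same profile, and the 3 densest windows lie on chromosome 5 between 9.5 and 12 Mb.

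The listed peaks lay where input chromatin itself gave many tags. The median input background at a peak was 141 tags in replicate 1 and 137 in replicate 2, 8.58 and 8.56 times the genome-wide average. The background exceeded 2 times the average at 96.3% and 96.0% of peaks, 5 times at 77.3% and 77.5%, and 10 times at 40.1% and 40.3%. Among peaks with a fold of at least 3 it exceeded 2 times at 64.3% and 69.3%, but 5 times at only 6.01% and 13.5%. Fold enrichment fell as background rose (Spearman's rho across peaks −0.67 in both lists), from a median of 2.37 and 2.47 below 2 times the average to 1.53 and 1.55 above 10 times. The background is the denominator of the fold, so counting error in it can make rho negative, by an amount not measured here. The threshold of the test and the ceiling on tags both bear on this relation: 4128 and 3774 peaks had at least 450 of the 500 tags that a position can hold, and none of these had a fold above 2.79 in replicate 1 or 2.39 in replicate 2.

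**Figure D4:**
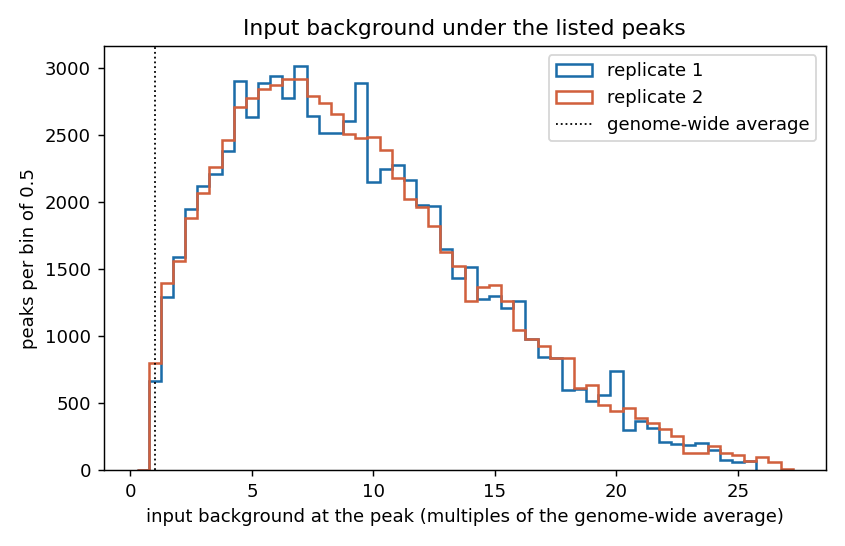
Number of peaks (y axis, bins of 0.5) by input background at the peak, in multiples of the genome-wide average (x axis), for replicate 1 and replicate 2; the dotted line marks the average. The medians are 8.58 and 8.56 times the average, and 3.72% and 3.99% of the peaks lie below 2 times it.

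Many peaks at separate places had identical values. In 6348 of the shared pairs (11.3%), the tag number, fold enrichment and width were equal to those of at least one other pair in both lists at once. They formed 2204 sets, of which 1254 (56.9%) spanned more than one chromosome. The largest set held 40 peaks on 11 chromosomes, each with 309 tags, a fold of 1.63 and a width of 68 bp in replicate 1, and 291 tags, a fold of 1.82 and a width of 56 bp in replicate 2. Its first member was on chromosome 1 at 2509911 to 2509978. The next set held 35 peaks on 11 chromosomes, with 213 and 203 tags and folds of 1.73 and 1.85. The third held 29 peaks on 11 chromosomes, with 360 and 334 tags and folds of 2.19 and 2.42. When the replicate 2 partners were permuted among pairs of similar replicate 1 values, which kept most of the correlation between the lists, at most 95 to 2993 peaks were identical in both lists, depending on how narrowly the pairs were grouped. None of the 12 named regions belonged to such a set, which also needs equal widths. However, 2 of them had tag numbers found at 3 other loci each, with similar folds and other widths. In replicate 1 the named region on chromosome 6 and that at 35639867 on chromosome 3 shared a fold of 4.40 and a −log10 q of 80.1. Their folds in replicate 2 were 4.04 and 3.81, and their widths in replicate 1 were 236 and 71 bp. Whether these 4 loci are copies of a repeated sequence was not tested.

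**Figure D5:**
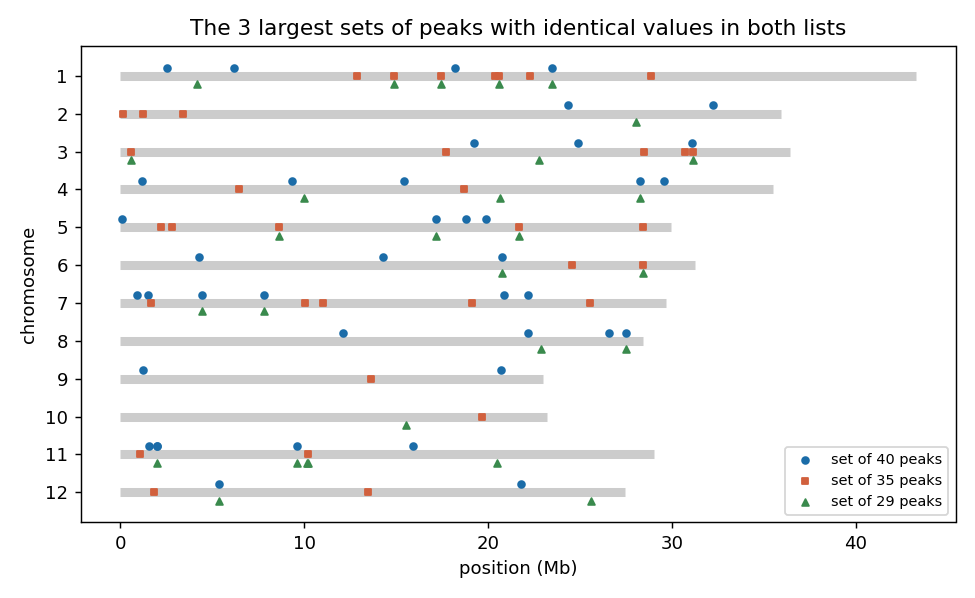
Positions (x axis, Mb) on the 12 chromosomes (y axis, grey bars up to the last listed peak) of the 3 largest sets of peaks with identical tag number, fold enrichment and width in both lists. The sets of 40, 35 and 29 peaks are each scattered over 11 chromosomes.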

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

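More peaks were shared than under random placement in all 11 other settings in which this was tested (permutation p = 0.00498 in each), with ratios from 18.4 to 384. The setting with a fold of at least 3 gave the highest. No placement kept the input background at a peak, so these ratios do not separate shared enrichment from shared sites of high background. Settings on background, its average, width, tag ceiling and identical peaks, and the joining of peaks, were added after the data were examined. The number of shared peaks stayed within 1.5 times of 56179 in 7 settings. It was 440 with a fold of at least 3, 1694 with the 5000 highest folds of each list (33.9% of them), 813 with a background under 2 times the average in each list (30.1%) and 23734 with peaks of at least 100 bp; each uses fewer peaks. Spearman's rho was 0.77 to 0.84 in 8 settings (1 of them on −log10 q in place of fold enrichment), but 0.25 with a fold of at least 3, 0.29 with the 5000 highest folds and 0.52 with the low background; rho of −log10 q in these was 0.86, 0.83 and 0.64. The share of peaks above 2 times the background fell from 96.3% to 64.3% in replicate 1 and from 96.0% to 69.3% in replicate 2 among folds of at least 3. It was 95.5% and 95.2% with the background averaged over the span of the listed sequences, and 96.1% and 95.9% with identical peaks counted once. Without the condition on width, 19203 peaks were identical in both lists. The permutations counted sets of equal width, so they give no chance level for this number. Joining peaks under 200 bp apart left 52044 and 51645 regions. Alternatives for genomic distribution, the CArG motif, gene lists and product classes were not run, since peaks were not placed relative to genes or sequence. Sharing needs both lists, so neither replicate could be left out. No paired analysis was possible because the lists hold peaks already called against the input of the same number. At this depth the smallest folds called at the average background were 1.86 and 1.74, and the ceiling of 500 tags limits folds where background is high.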

Other observations

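All tests in this part, that of the power of the peak test included, were chosen after their results had been seen. The number of peaks at under 2 times the genome-wide input background was compared with that of all peaks along the chromosomes. Over the 740 windows of 500 kb the number of these low-background peaks followed that of all peaks weakly. Spearman's rho was 0.19 in replicate 1 and 0.14 in replicate 2, while the low-background numbers of the lists followed each other with a rho of 0.59. At a median of 3 such peaks per window, counting error can weaken the former, and peaks found in both lists add to the latter. A separate distribution is therefore not shown. The window with the most was on chromosome 8 from 11 to 11.5 Mb, with 24 and 21 such peaks against a median of 3 in both lists. Chromosome 3 from 18.5 to 19 Mb held 14 and 16, and chromosome 7 from 20 to 20.5 Mb held 13 and 16. The 39 unplaced sequences, which span 0.883 Mb up to their last peaks, held 593 and 604 peaks per Mb, more than any chromosome.

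Identical peaks at separate loci may come from reads counted at every copy of a repeated sequence. Their number, 6348, was above the highest of 100 permutations among similar pairs in all 5 groupings, by 66.8 times in the widest (95 peaks) and 2.12 times in the narrowest (2993 peaks, where copies can meet again), which argues against chance agreement as the whole cause. Around the sets of at least 5 peaks, a median of 68.4% of a set's members had a neighbouring peak at one fixed distance within 5 kb (in steps of 5 bp), against 25% in random sets of the same sizes, as copies of one longer element would give. For example, 9 members of the set of 35 peaks lay exactly 2571 bp from a member of the set of 29. The distance was less uniform for 9 members of the set of 40, which lay 2453 to 2565 bp from a member of the set of 29. Which elements these are was not tested, and if reads were placed at every copy, enrichment at 1 copy would appear at all of them.

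Whether the power of the test alone accounts for the high input background under most peaks could not be decided. Peaks at under 1.1 times the genome-wide background were called from folds of 1.86 in replicate 1 and 1.74 in replicate 2, and among all peaks at or above those folds 61.3% and 66.6% lay above 5 times the background. An average allows at most 20% of the genome to lie above 5 times itself, on the effective genome size of the headers. That limit holds for input tags at a position, whereas the background at some peaks was a regional or genome-wide average. The folds of 1.86 and 1.74 are also only the smallest called, not folds at which every region would be called. At folds of at least 3 only 6.01% and 13.5% of peaks lay above 5 times, under that limit. The ceiling on tags limits folds where background is high, which can keep peaks of high background out of this group. These low shares therefore cannot decide for or against power. Backgrounds above 2 times held 64.3% and 69.3% of the peaks with folds of at least 3. With the average over the listed sequences the shares were 59.4% and 65.3%. At single positions an average allows at most 50% of the genome above 2 times itself. For the reasons given, the comparisons do not exclude power. Repeated sequence may contribute to the high background, since identical peaks had a median of 12.1 times the average against 8.82 for the other shared peaks. The latter were high as well, however. Whether OsMADS27 binds repeats or the pull-down favours them over input stays open: no pull-down from untagged plants is among the 4 samples, and no biological explanation was tested.

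The replicates could be parts of one library, or separate pull-downs that vary little. Sampling under the tag ceiling, with tags spread evenly over the positions, would give ratios of observed to Poisson variance of 0.665 and 0.965. The first is for the 44503 distinct pairs with summits at most 50 bp apart and a whole-number background, the second for those of under 200 tags. The observed ratios of pulled-down tags were 0.581 and 0.746. The pairs were selected by a call in both lists and by close summits, which can lower the ratios by an amount not measured here. The ratios therefore show neither that sampling alone sets the differences nor whether the libraries are one or separate. Peaks with a −log10 q of at least 30 were nevertheless missing from the other list in 12.2% and 17.4% of cases, and a candidate explanation is the minimum length of 50 bp, since 78.7% and 78.8% of those missing were 60 bp or shorter, against 33.4% and 28.6% of those shared. Most strong peaks of that length still had a partner (75.3% and 63.3%). Strong peaks of at least 100 bp were shared in 95.6% and 94.4% of cases, which leaves some losses that length need not account for.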
